A study of Mus musculus with 8 samples.

How the data were processed

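The series measured gene expression in whole tibialis anterior muscle of male C57BL/6 mice, 8 days after the muscle was frozen with a chilled metal probe for 8 seconds. Foxp3-Cre/ST2 flox mice were set against Foxp3-Cre/ST2 WT mice, with 4 samples in each group. Per the labels' protocols, tissue was dissected and trimmed, RNA was extracted with TriZol, amplified with an Ambion kit and hybridised to Affymetrix Mouse Gene 1.0 ST arrays, with 1 array per sample. The labels number the samples within each group but do not state that each came from a separate animal, so p-values measure the spread between these samples, which may be technical.

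The authors deposited a table of probeset intensity values. Per the submitters' processing notes, these were made with RMA in Affymetrix Power Tools, a method that corrects the background, makes the distributions of the arrays alike and summarises the probes of each probeset. Versions, genome build and any filter on rows are not given in the sources used here. The deposited intensities are on a linear scale, as shown by their range from 5.81 to 19080, and their distributions differ slightly between arrays, so a step after the normalization between arrays cannot be ruled out. RMA compresses large changes of dim probesets and assumes that most genes do not change, so a shift shared by most transcripts would not be visible. For arrays, the number of arrays limits the precision.

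The base 2 logarithm of each value was taken without a pseudocount. The table held 24922 rows. Gene names came from the platform annotation: 21425 rows had 1 gene symbol, 1399 had several and 2098 had none in the annotation used here. Only rows with 1 symbol were named, and they covered 19752 genes, of which 921 had more than 1 row. Of these rows, 21347 had a gene identifier found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed in the update. That table was used only for names and for which genes neighbour each other, and no coordinates are given. Rows whose mean over the 8 arrays lay below the 25th percentile of all rows, a log2 value of 6.35, were left out. For each gene the row with the highest mean was kept, which left 15007 genes. No array had more than 14 values identical to those of another array, so no array was a copy.

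Groups were compared with limma 3.58.1 in R 4.3.3 (linear model on group alone, empirical Bayes with the default prior), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are log2 differences, flox minus WT, with limma's standard error. An unadjusted p for a single gene is limma's. Gene lists were fixed in 4 families: muscle, immune, stroma and control. The 34 lists held 756 entries, of which 626 were tested, and 32 lists had at least 5 tested genes. The remaining pair, erythroid genes and male-specific genes with Xist, had 2 and 3 tested genes and were not tested as lists. For each list and array, the mean over the list of log2 values centred per gene was computed. The shift is the difference of the group means, with a standard error from the group variances. It was tested with an exact two-sided permutation test over all 70 assignments of the labels, which cannot give a p below 0.0286, with Benjamini-Hochberg adjustment over the 32 lists. With this floor, a list can pass 0.05 after adjustment only if many lists lie at the floor together. Each list was also compared with all other genes by camera, with a preset correlation between genes of 0.01 and again with an estimated correlation, and tested by fry, both from limma and adjusted over the lists. Fry asks whether the genes of a list move, on balance, to 1 side and does not compare the list with other genes. Some lists share a few genes: at most 3 are shared by any pair.

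The genes named were set by rule. They were 4 genes fixed by name, the 10 genes in each direction with the largest change among those past the threshold with groups that did not overlap, and up to 4 members of each list with the smallest unadjusted p. Where fewer than 10 passed, the places were filled by the smallest unadjusted p under 0.05 among genes whose groups did not overlap. Of the 4 genes fixed by name, Foxp3 and Il33 were tested. The floxed gene itself and the fourth gene had no row naming that gene alone among the rows used, and they are not analysed here. The arrays therefore carry no direct check of the deletion, which would touch only regulatory T cells, a small part of whole muscle. Cd3e, Mir341 and the genes named for a difference by sample number or for a single array were named after their values were seen. A second list of clock genes, a second list of skin genes and the set of genes that neighbour the floxed gene were fixed before their own values were looked at.

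The fit was tested on simulated data for this comparison of 4 against 4 arrays over 15007 genes. With the real arrays' residuals, 55 of 67 genes changed 1.5-fold (82.1%) were recovered at the threshold. So were 64 of 67 changed 2-fold and 64 of 66 changed 3-fold, with 0 false calls. These residuals were centred within each group, so unchanged genes had no group difference and could not be called. The 0 false calls therefore do not measure an error rate. The added changes were also fitted without error, so these shares do not measure the power of a real comparison. With independent noise the shares were 82.1%, 98.5% and 98.5%, with 11 false calls.

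The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were no filter or a filter at the 50th percentile, the mean of a gene's rows, quantile normalization again, centring on the median, cyclic loess, another variance prior, array weights, the sample number as a block, the sarcomere list as a covariate, each array left out in turn (with the filter applied again, so that a list could gain or lose genes near it), log2 of the value plus 16, an adjusted p under 0.1, a minimum of 1.5-fold, limma's treat at 1.2-fold, fry, an estimated correlation and the median over a list. A covariate for macrophage content and a block that sets the samples numbered 1 and 2 against those numbered 3 and 4 were added after seeing the data. Samples of the same number were also checked for shared deviations from their group means. The correlations were -0.002, 0.352, 0.253 and 0.0422 for numbers 1 to 4, so the numbers were not taken to pair the samples.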

Results

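Injured muscle was profiled to ask what ST2, the receptor for the alarm cytokine interleukin-33, does in regulatory T cells during muscle regeneration. Regulatory T cells express the transcription factor Foxp3, and Foxp3-Cre removes a floxed gene in them. The tibialis anterior, a fast muscle of the lower leg, was taken 8 days after freezing injury, from 4 ST2 flox and 4 ST2 WT samples. The labels give an age of 10 weeks and the description of the series 2 months. Median intensity per array lay between 185 and 189. Arrays correlated as well between groups (median r = 0.991 over 16 pairs, across genes) as within them (median r = 0.991 over 12 pairs). Y-linked transcripts were present and the X-inactivation transcript Xist was low on all 8 arrays, with log2 levels of 9.79 to 10.3 for Eif2s3y and 5.76 to 6.09 for Xist. The smallest log2 level of Uty was 8.57 and that of Kdm5d was 7.80.

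The mean over the cell cycle genes was higher in ST2 flox muscle. Of the 33 cell cycle genes tested, 32 had a higher mean in flox, and the group means of the list differed by 0.19 log2 (SE 0.07, n = 4 and 4), or 1.14-fold. Each of the 4 flox arrays lay above every WT array, with list means of 0.258 and 0.181 on flox arrays 2 and 3 but only -0.035 and -0.021 on flox arrays 1 and 4, against -0.109 to -0.081 on the WT arrays. The members with the smallest p were Prc1, which organises the spindle midzone (0.38, SE 0.10), Cdk1, the kinase that drives entry into mitosis (0.40, SE 0.11), Mcm4, a subunit of the replicative helicase (0.30, SE 0.08), and Top2a, which untangles replicated DNA (0.36, SE 0.12). Cdk1 and Mcm4 were higher on all 4 flox arrays than on any WT array, while Prc1 and Top2a overlapped between the groups. The exact permutation p of the list shift was 0.0286, the smallest that the test can give, and 0.457 after Benjamini-Hochberg adjustment over the 32 lists. Only 2 lists reached that floor, so the adjusted p could not pass 0.05 however far apart the groups lay, and it does not speak against a shift. Camera placed the list above other genes with an adjusted p of 3.12e-16, and the call was lost when the correlation was estimated (adjusted p = 0.457 with an estimated correlation). In limma 0 members passed 0.05 adjusted over the list alone (smallest adjusted p 0.0574) or over all genes, and 17 members, all higher, had an unadjusted p under 0.05. Without any of the 4 WT arrays in turn the exact p was 0.0857, at shifts of 0.19 to 0.20. With 4 against 3 arrays, placing flox array 1 or 4 with the WT arrays gives a larger difference, which raises this p. The rise does not show that the shift rests on a WT array.

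The group means of the T cell list differed by 0.15 log2 (SE 0.05, exact permutation p = 0.0286, 0.457 after adjustment over the lists), with 12 of 16 genes higher. The list means were 0.085, 0.216 and 0.039 on flox arrays 1 to 3 and -0.038 on flox array 4, close to the highest WT array (-0.087 to -0.054 on the WT arrays). The shift was 0.30 with the filter at the 50th percentile and 0.10 with the macrophage list as a covariate, an alternative added after seeing the data. Its leading members were Cd3g, a chain of the CD3 complex (0.85, SE 0.28), Il7r, the interleukin-7 receptor (0.29, SE 0.10), the coreceptor Cd4 (0.20, SE 0.08) and Thy1 (0.30, SE 0.14). Cd3g was uneven: its log2 level was 7.63, 7.92 and 7.36 on flox arrays 1 to 3, 6.27 on flox array 4, and 6.32 to 6.60 on the WT arrays. Another chain of the complex, Cd3e, lay between 7.29 and 7.48 on all 8 arrays. The shift of the other 15 genes was 0.10 (SE 0.04, exact permutation p = 0.0286). Camera gave the T cell list an adjusted p of 6.00e-04, which became adjusted p = 0.400 with an estimated correlation. In limma 0 members passed 0.05 adjusted over the list alone and 3 had an unadjusted p under 0.05. The exact p of the T cell shift rose to 0.0571 without any single WT array, with the filter at the 50th percentile or with median centring, to 0.0857 with quantile normalization and to 0.143 with cyclic loess. Without a WT array the shift was 0.15 to 0.16, and the test of 4 against 3 arrays is uneven in the same way as for the cell cycle list.

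The natural killer and cytotoxic list differed by 0.20 (SE 0.07, exact permutation p = 0.0857, 0.774 after adjustment over the lists), with 4 of 6 genes higher. Its member Gzmk, a granzyme of cytotoxic lymphocytes, was 0.32 higher in flox (SE 0.09) and was the only member of any of the 32 lists to pass 0.05 adjusted over the list alone (limma adjusted p 0.0296; 0.912 over all genes). With each of the 32 lists adjusted on its own, a single such member is no more than chance would give. The WT mean of Gzmk, 6.41, lay just above the filter at 6.35. Ccl5, a chemokine that attracts T cells, differed by 0.48 (SE 0.21) and Nkg7 by 0.46 (SE 0.21). The list's camera call (adjusted p 0.0413) was lost when the correlation was estimated (adjusted p = 0.457 with an estimated correlation). The call was also lost with the sample number as a block, and without any single array other than flox array 2. Antigen presentation genes were higher for 14 of 16 members, by 0.17 as a list (0.11 without flox array 2 and 0.24 without flox array 4; SE 0.08, exact permutation p = 0.114; camera adjusted p 6.36e-06, and adjusted p = 0.400 with an estimated correlation). This list holds dendritic cell and MHC class II genes and is called the antigen presentation list in the text. Among its members were the class II chain H2-Eb1 (0.32, SE 0.11) and its master regulator Ciita (0.16, SE 0.06). Others were Fscn1 of mature dendritic cells (0.27, SE 0.09) and the integrin Itgax (0.16, SE 0.07). In limma 0 members of this list passed 0.05 adjusted over the list alone and 5 had an unadjusted p under 0.05.

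**Figure D1:**
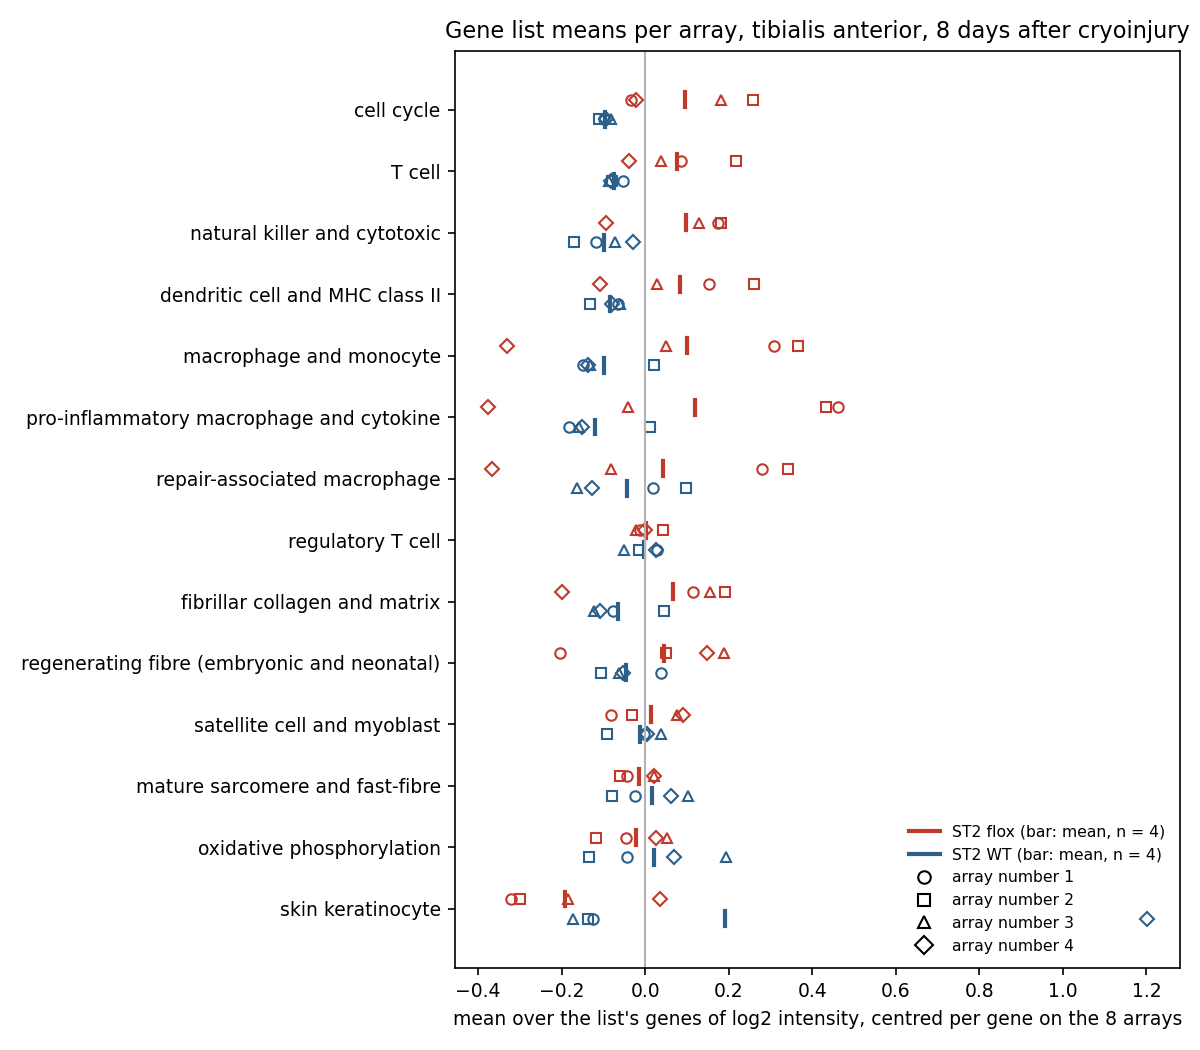
Mean of 14 gene lists on each of the 8 arrays, in log2 intensity centred per gene. Symbols are arrays by sample number and bars are group means (n = 4). The cell cycle and T cell lists are higher on all 4 flox arrays than on any WT array, macrophage lists spread widely over the flox arrays, and the skin list is high on WT array 4 alone, at 1.201.

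Macrophage genes were higher on average but varied among the flox samples by more than the groups differed. All 23 macrophage and monocyte genes had a higher mean in flox, and the list differed by 0.20 (SE 0.16, exact permutation p = 0.257). Its per-array means were 0.31, 0.37 and 0.05 on flox arrays 1 to 3 and -0.33 on flox array 4, against -0.15 to 0.02 on the WT arrays. The list differed by 0.34 without flox array 4 (exact permutation p = 0.0286, the smallest possible), by 0.13 without flox array 1 and by 0.11 without flox array 2. The leading members were the endotoxin coreceptor Cd14 (0.24, SE 0.09) and the protease Ctss (0.25, SE 0.11; 0.15 without flox array 2). The pro-inflammatory list behaved alike, with 12 of 13 genes higher and a shift of 0.24 (SE 0.21, exact permutation p = 0.343; 0.38 without flox array 4, 0.13 without flox array 1 and 0.14 without flox array 2). There Ptgs2 differed by 0.33 (SE 0.14), Nos2 by 0.21 (SE 0.10) and Il1b, the gene of interleukin-1 beta, by 0.66 (SE 0.31). Without flox array 2 these differences were 0.22 for Ptgs2 and 0.13 for Nos2, and Il1b differed by 0.43 without flox array 1. Camera called these lists with adjusted p of 2.38e-07 and 0.00105, and neither call held (adjusted p = 0.747 with an estimated correlation for each). The repair-associated macrophage list shifted by 0.09 (SE 0.18, exact permutation p = 0.600), with Tgfb1, a growth factor that drives matrix deposition, 0.18 higher (SE 0.05) and apart on all arrays. Neutrophil genes shifted by 0.14 (SE 0.17, exact permutation p = 0.400), complement and phagocyte lysosome genes by 0.12 (SE 0.15, exact permutation p = 0.429) and interferon response genes by 0.10 (SE 0.16, exact permutation p = 0.571). Single arrays moved these lists both ways. Over the fits without each array, the shift of the repair-associated list ranged from -0.02 (without flox array 2) to 0.22 (without flox array 4), that of complement genes from 0.04 (flox array 1) to 0.25 (flox array 4), that of interferon response genes from 0.03 (flox array 3) to 0.22 (flox array 4) and that of neutrophil genes from 0.05 (flox array 1) to 0.24 (WT array 2).

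Regulatory T cell genes did not separate the genotypes. The list shifted by 0.01 (SE 0.02, exact permutation p = 0.800), with 6 of 12 genes higher. Of its 20 entries only these 12 were tested. Regulatory T cells are a small part of whole muscle, so a change in them may not be visible here. Foxp3 differed by -0.01 (SE 0.08; -0.05 to 0.07 over the fits without each array), with means of 7.35 in flox and 7.36 in WT, and Il33 by 0.06 (SE 0.19). Il33 was above every WT array (7.92 to 8.12) on flox arrays 1 to 3 (8.52, 8.21 and 8.27) and below them on flox array 4 (7.42), so that its difference was 0.29 without flox array 4 (limma adjusted p 0.152) and -0.08 without flox array 1. The interleukin-33 and ST2 axis list, tested without the floxed gene, shifted by 0.04 (SE 0.06, exact permutation p = 0.600), and by 0.00 to 0.09 without flox array 1 or 4. B cell genes shifted by -0.02 (SE 0.04, exact permutation p = 0.571), although the median member was 0.01 higher, and eosinophil and mast cell genes by -0.01 (SE 0.10, exact permutation p = 0.943), where camera put the list marginally up and the shift was -0.08 without flox array 1 and 0.05 without flox array 4.

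Matrix genes were higher for 38 of 43 members, by 0.13 as a list (0.22 without flox array 4; SE 0.10, exact permutation p = 0.257; camera adjusted p 2.38e-07, and adjusted p = 0.747 with an estimated correlation). Serpinh1, the collagen chaperone (0.27, SE 0.08), and Col15a1 (0.17, SE 0.06) were higher on all 4 flox arrays than on any WT array, and Thbs1 differed by 0.33 (SE 0.13; 0.21 without flox array 2). Of the muscle lists, regenerating fibre genes were higher for 16 of 20 members, by 0.09 (SE 0.09, exact permutation p = 0.343; 0.17 without flox array 1 and 0.04 without flox array 3), with Igfn1 at 0.22 (SE 0.09) and Csrp3 at 0.43 (SE 0.24; 0.20 without flox array 2). Mature sarcomere and fast-fibre genes were lower for 29 of 35 members, by -0.03 (SE 0.05, exact permutation p = 0.486), and glycolysis genes for 16 of 17, by -0.08 (SE 0.06, exact permutation p = 0.257). Oxidative phosphorylation genes were lower for 43 of 50 members, by -0.04 (SE 0.08, exact permutation p = 0.600), a direction that rested on WT array 3, without which the shift was 0.01. Sarcomere genes likewise shifted by -0.002 without WT array 3, and glycolysis genes by -0.04 without flox array 2. In limma 0 members of these lists passed 0.05 adjusted over the list alone, and 6 matrix genes, 1 regenerating fibre gene, 1 sarcomere gene and 1 oxidative phosphorylation gene had an unadjusted p under 0.05. Satellite cell and myoblast genes shifted by 0.03 (SE 0.05, exact permutation p = 0.571), and their list means overlapped between genotypes. These were -0.08 and -0.03 on flox arrays 1 and 2, 0.08 and 0.09 on flox arrays 3 and 4, and -0.09 to 0.04 on the WT arrays. The myogenic factor Myf5 differed by 0.12 (SE 0.07), and by 0.08 without flox array 3 or WT array 4.

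The remaining lists moved by less than 0.1 log2 with an exact permutation p of at least 0.229, except skin. Pericyte and smooth muscle genes shifted by 0.06 (SE 0.04), endothelial genes by 0.04 (SE 0.04), slow-fibre genes by 0.04 (SE 0.14) and immediate early genes by 0.04 (SE 0.04). Endothelial list means ran from 0.10 on flox array 1 to -0.08 on WT array 2. Slow-fibre list means ran from 0.19 on flox array 2 to -0.33 on flox array 1, and immediate early list means from 0.08 on WT array 3 to -0.08 on WT array 1. Fibro-adipogenic progenitor genes shifted by 0.02 (SE 0.14), ribosomal protein genes by 0.02 (SE 0.04), atrophy and denervation genes by 0.02 (SE 0.03) and tendon genes by -0.01 (SE 0.03). Citric acid cycle and fatty acid oxidation genes shifted by -0.02 (SE 0.09), Schwann cell genes by -0.04 (SE 0.05) and adipocyte genes by -0.05 (SE 0.08). Some of these small shifts hung on 1 array: fibro-adipogenic progenitor genes shifted by 0.15 without flox array 4 (camera adjusted p 6.22e-05) and by -0.08 without flox array 1 (0.0390), slow-fibre genes by 0.16 without flox array 1 (1.49e-04) and adipocyte genes by -0.11 without flox array 1 (3.50e-04) but by -0.00 without flox array 2. Citric acid cycle and fatty acid oxidation genes shifted by -0.09 without WT array 2 (camera adjusted p 9.54e-05) and by 0.04 without WT array 3. These camera values used the preset correlation, and the fits without an array were not repeated with an estimated correlation. Over all arrays, camera with an estimated correlation gave these lists an adjusted p of 0.869 to 0.904. Skin keratinocyte genes were lower in flox for all 9 members, by -0.38 (SE 0.35, exact permutation p = 0.314), with WT array 4 at 1.201 and the other WT arrays between -0.17 and -0.12, and by -0.05 without WT array 4. In all, camera called 17 of the 32 lists, 13 higher and 4 lower (sarcomere, glycolysis, oxidative phosphorylation and skin). With an estimated correlation 0 lists passed (smallest adjusted p 0.400) and 3 had an unadjusted p under 0.05, namely the T cell, antigen presentation and cell cycle lists. Fry also called 0 lists (smallest adjusted p 0.179), with 3 at an unadjusted p under 0.05.

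Among single genes the differences were small. The 10 genes with the smallest p among those higher on all 4 flox arrays were the histone gene H2ac15 (0.38, SE 0.09), the kinetochore scaffold Knl1 (0.41, SE 0.09), the class II chain H2-Eb2 (0.24, SE 0.06), Mir300, Nudt5, BC028528, Stap1 (0.46, SE 0.12), Mir382 (0.43, SE 0.11), the chemokine receptor Cxcr4 (0.23, SE 0.06) and Zdhhc15. Those lower on all 4 flox arrays were Zfp940 (-0.27, SE 0.06), the muscle gene Fsd2 (-0.21, SE 0.05), Tlcd4 (-0.29, SE 0.07), the calcium channel subunit Cacna2d4 (-0.34, SE 0.09), the smooth muscle actin regulator Lmod1 (-0.23, SE 0.06), Nxph1, Anks1b, 2810021J22Rik, the intermediate filament gene Synm (-0.19, SE 0.05) and Slc24a1. None of these 20 genes passed the threshold, each with a limma adjusted p of 0.912. Over all 15007 genes limma called 0, and 569 genes had an unadjusted p under 0.05 (304 higher, 265 lower) where 750 would be so by chance. The 2 groups did not overlap for 295 genes, or 1.97%, where chance gives 2.86%, and only 7 genes differed by 1.5-fold or more at any p.

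Leaving out flox array 4 raised the genes at an unadjusted p under 0.05 to 3003 and let 2 genes pass in limma: Cd3g, higher by 1.19 (SE 0.12, adjusted p 0.0272), and the lysosomal protease Ctsh, higher by 0.56 (SE 0.06, adjusted p 0.0272; 0.32 over all arrays). On flox array 4 itself each of these genes lay below every WT array. Cd3g was at 6.27 there against 6.32 to 6.60 on the WT arrays, and Ctsh at 8.59 against 8.90 to 9.06. Leaving out flox array 2 or WT array 1 lowered the genes at an unadjusted p under 0.05 to 246 and 276, with 0 genes past the adjusted threshold.

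The samples also differed by number. A grouping of the samples numbered 1 and 2 against those numbered 3 and 4, singled out after all 35 ways to part the 8 arrays into sets of 4 had been fitted, gave 51 genes past the adjusted threshold in limma, 24 higher and 27 lower. Genes of the circadian clock were among them. Ciart, a clock repressor, was 1.499 log2 higher on numbers 1 and 2 (SE 0.13), the clock output factor Dbp 0.89 (SE 0.09), Per3 0.50 (SE 0.08) and Per2 0.42 (SE 0.07), while Arntl, the clock's core activator, was lower by -0.56 (SE 0.10). The matrix protease Mmp13 was 2.09 higher (SE 0.32), the acute-phase gene Serpina3n 1.54 (SE 0.22) and the chemokine Cxcl13 0.98 (SE 0.10). Each genotype had 2 samples of either kind, so the grouping did not shift the genotype means, and with it as a block limma called 0 genes for genotype (smallest adjusted p 0.753) and 929 at an unadjusted p under 0.05.

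Within numbers 1 and 2 the cell cycle list was 0.22 higher in flox and within numbers 3 and 4 it was 0.17 higher. The T cell list differed by 0.22 and 0.09. Permuting genotype within these sets gave an exact p of 0.0556 for each list, the smallest that 36 assignments allow. The macrophage list differed by 0.40 within numbers 1 and 2 and by -0.01 within numbers 3 and 4, the pro-inflammatory list by 0.53 and -0.05, the antigen presentation list by 0.31 and 0.03, the natural killer list by 0.32 and 0.07 the matrix list by 0.17 and 0.09 and the regenerating fibre list by -0.04 and 0.23. With 2 samples per genotype in each set these differences between sets were not tested for the lists, and 0 genes passed 0.05 in limma for an interaction of set and genotype. At an unadjusted p under 0.05 there were 2303 genes, where chance gives 750 on average. Such counts vary widely on these arrays: plain splits into sets of 4 gave 82 to 3285. The 2303 is therefore no evidence of an interaction.

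**Figure D2:**
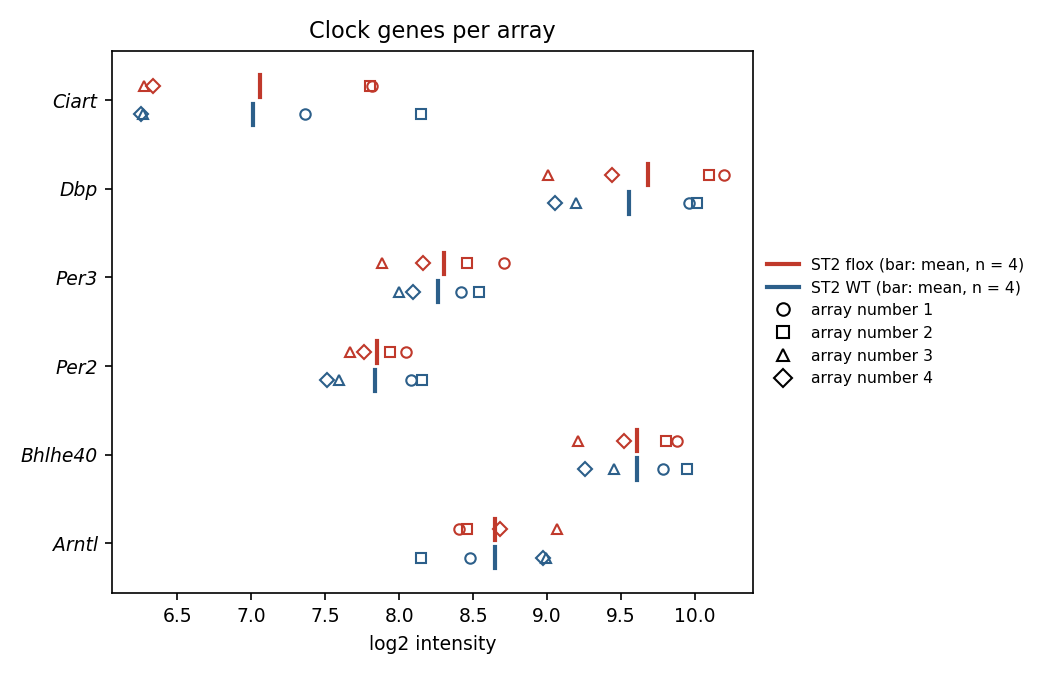
Log2 intensity of 6 clock genes on each of the 8 arrays. Symbols are arrays by sample number, colours are genotypes and bars are group means (n = 4). Ciart, Dbp, Per3, Per2 and Bhlhe40 are higher, and Arntl lower, on numbers 1 and 2 than on numbers 3 and 4 in each genotype.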

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

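The tests of the ST2 WT genotype for the skin genes and of WT array 4 for the cell cycle genes, and the macrophage list as a covariate, were chosen after the results were seen. A group of 4 arrays was singled out when its extreme array lay far from the nearest of the others relative to the group's range. This happened in 14 of 234 groups examined, and chance alone gives about 12, so single cases carry little weight.

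Skin transcripts were high on WT array 4. The skin keratinocyte list stood at 1.201 there, with all 9 tested members highest on that array, Krt10 at 9.66 against 7.13 to 7.20 on the other WT arrays, and Krt77 at 9.03 against 7.08 to 7.19. ST2 genotype as the source is argued against, since 3 of the other WT arrays lay within the range of the flox arrays. A piece of skin left on the dissected muscle may account for it: a second list of epidermis and hair genes exceeded the other WT arrays by a mean of 0.490 log2, just under the 0.5 set in advance, so this explanation stays open. In that list 15 of 23 genes were highest on WT array 4, where chance gives 12.5%, led by the cornified envelope gene Lce1c (2.72 log2) and Asprv1 (1.41), while the hair genes Krtap3-1 (-0.08, among the brightest of the list), Krt71 (-0.13), Krt73 (0.00) and Krt27 (0.07) and the epidermal gene Aqp3 (-0.01) exceeded the other WT arrays by less than 0.1 or not at all.

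The mean over the cell cycle genes was higher on all 4 flox arrays than on any WT array. The scale of the array values and the high skin transcripts of WT array 4 are argued against as the whole cause. Quantile normalization kept 99.9% of the shift and leaving out WT array 4 kept 100.4%. More immune cells in the flox samples could not be excluded: with the macrophage list as a covariate 80.7% of the shift was kept, at 0.15 (SE 0.08). Nor could chance, because 2 of the 35 ways to part the 8 arrays gave a camera p as small (-log10 p 17.0 for genotype and 17.2 for flox array 1 with WT arrays 2 to 4).

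For the T cell list, 1 of 35 ways to part the arrays, genotype itself, gave a camera p as small, with -log10 p of 4.03 against at most 3.96. The list had been picked out of 32 because it separated the genotypes, so chance was not excluded. Its exact permutation p after adjustment over the lists was 0.457, but with only 2 lists at the floor of the test it could not have passed 0.05. With the macrophage list as a covariate its shift fell from 0.15 to 0.10.

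Macrophage genes spread widely among the flox arrays, over 0.70 log2 (1.62-fold) against 0.17 over the WT arrays. The scale of the array values is argued against, since 90.0% of the range over the flox arrays was kept after quantile normalization. A varying amount of intact fibre in the sample may contribute: across the 8 arrays the list ran against the sarcomere list with Pearson r = -0.589 (permutation p = 0.128) and Spearman rho = -0.548 (permutation p = 0.171), the only relation computed. Without flox arrays 1 and 2, the farthest from the median, r was -0.336, so the relation rests on those samples and the explanation stays open. No biological explanation was tested for a spread within a genotype.

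The other cases are given as values. WT array 2 was high for the macrophage list (0.0209 against -0.15 to -0.13), the pro-inflammatory list (0.0122 against -0.18 to -0.15) and Il1b (6.98 against 6.18 to 6.26). WT array 3 was low for the interleukin-33 and ST2 axis list (-0.0931), and flox array 1 was low for the immediate early list (-0.0318). Flox array 4 was low for Ccl5 (8.26 against 9.09 to 9.24), Zbp1 (8.04) and Ddx58 (8.77), and higher than the other flox arrays for Krt77 (7.21 against 6.91 to 6.92). WT array 1 was low for Nudt5 (7.60) and high for Cxcl1 (7.36).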

How the results depend on the processing

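The macrophage covariate and the block that sets numbers 1 and 2 against 3 and 4 were chosen after seeing the data; the other alternatives were planned. The count of genes past the threshold in limma was 0 in 22 of 23 other fits and ranged from 0 to 2 over the fits without each array, with 2 without flox array 4 (smallest adjusted p 0.0272, against 0.336 to 1.00 in the other fits). Genes at an unadjusted p under 0.05 numbered 569, but 344 with the filter at the 50th percentile, 1932 with array weights, 929 with numbers 1 and 2 against 3 and 4 as a block, 2 with treat at 1.2-fold and 246 to 3003 without each array. Camera called 17 lists, 9 to 18 without each array (9 without WT array 3 or 4, 10 without flox array 2) and 16 with numbers 1 and 2 against 3 and 4 as a block, but 0 with an estimated correlation and 0 with fry in its place, settings that allow for genes moving together. The natural killer call was lost although its estimated correlation was negative (-0.149), so genes moving together do not account for every lost call. Camera called 6 lists in every fit with the preset correlation other than that block: T cell, macrophage, pro-inflammatory, antigen presentation, matrix and cell cycle. The T cell shift kept its sign but not its side of the threshold with the filter at the 50th percentile (0.30, fewer genes), quantile normalization (0.17), median centring (0.15) and cyclic loess (0.18); the cause was not tested. Without each array it ranged from 0.10 to 0.19, and the cell cycle shift from 0.14 to 0.23. With the macrophage covariate the shifts were 0.10 and 0.15. With the replicate block, limma called 0 genes (694 unadjusted) and camera 14 lists. The shifts of 0.15 and 0.19 stayed the same by design, because each number occurs once per genotype. The block changed no call of genes, and not every sample correlated best with its own number. Of 388 values of the 20 genes named by p, 0 changed sign. These genes were picked for groups that did not overlap, so leaving out an array could not reverse them. Their count of 0 therefore says little about robustness. Of 2891 values of all 147 named genes, 15 changed sign, and of 609 list shifts 32 did, all from shifts that had not passed. Beyond the T cell and cell cycle lists, 6 list shifts reached an exact p of 0.0286 in 1 fit each: natural killer with the median over the list (0.16) and, without flox array 4, macrophage (0.34), antigen presentation (0.24), complement (0.25), pericyte (0.09) and Schwann cell (-0.08). Shifts were not computed with the other variance prior, which does not enter them, and the alternatives for the floxed gene were not run, as it is not analysed here. Genes close to the filter, where signal is near background, are the least certain.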

Other observations

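The grouping of arrays by number and the test of the microRNA cluster were chosen after the results were seen.

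Between samples numbered 1 and 2 and samples numbered 3 and 4, 6 of the 32 lists lay apart on all 8 arrays (exact permutation p = 0.0286 each, 0.152 after Benjamini-Hochberg adjustment). Because the grouping was singled out from these same arrays, these p-values do not measure chance. The repair-associated macrophage list was higher by 0.37 (SE 0.10) and the neutrophil list by 0.37 (SE 0.10), while citric acid cycle and fatty acid oxidation genes (-0.19, SE 0.05), oxidative phosphorylation genes (-0.17, SE 0.04), sarcomere genes (-0.10, SE 0.02) and satellite cell genes (-0.10, SE 0.03) were lower. The macrophage (0.27), pro-inflammatory (0.36), complement (0.23) and antigen presentation (0.11) lists overlapped between the sets, with an exact permutation p of 0.114 to 0.371. Among single genes, Wfdc17 was higher by 1.24 (SE 0.18) and S100a4 by 0.70 (SE 0.11), whereas the transferrin receptor Tfrc (-0.69, SE 0.11), the glycogen-targeting subunit Ppp1r3c (-0.67, SE 0.08) and the opsin gene Opn1mw (-1.68, SE 0.11) were lower, all past 0.05 in limma.

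Some genes set a single array apart, and no shared function was tested for them. Flox array 4 was the lowest of the 8 arrays by at least 0.5 log2 for 38 genes, led by Sfrp4 (gap 1.18), Sfrp2 (0.89), Cmah (0.81), Ccn3 (0.76) and Ccl8 (0.75). Flox array 1 was the highest for 13 genes, led by Lcn2 (0.67), Saa3 (0.66), Hp (0.65), S100a9 (0.62) and Cyp2f2 (0.60). Flox array 2 was the highest for 5 genes, namely Dusp18 (0.68), Csrp3 (0.64), Arg1 (0.63), Ankrd2 (0.52) and Ccl6 (0.51), and the lowest for 2. The remaining arrays had at most 2 such genes, apart from the 20 highest on WT array 4.

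The clock genes led to the hypothesis that samples numbered 1 and 2 were taken at another time of day than samples numbered 3 and 4. A second list of 8 tested clock genes, none of which had drawn attention, was set before its own values were looked at. The genes that cycle with Dbp exceeded those that cycle with Arntl by 0.50 log2 more on numbers 1 and 2 (SE 0.07, exact permutation p = 0.0286), by 0.46 within flox and 0.53 within WT. Of the 8 genes, 7 moved in the predicted direction past 0.05 adjusted over the list alone in limma, among them Per1 (0.58, SE 0.15) and Nfil3 (-0.49, SE 0.11), and Nr1d1 (-0.06, SE 0.10) did not. The grouping had been singled out from these same arrays, with Dbp and Arntl among the genes past the threshold. These p-values for genes that cycle with Dbp or Arntl are therefore no independent test of the grouping. They show only that most other clock genes moved along with those 2. A difference in harvest time could give this pattern, though another difference that comes with it, such as separate cohorts, stays untested. The same contrast did not separate the genotypes (-0.01, exact permutation p = 0.971).

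Of the 35 ways to part the arrays into sets of 4, genotype gave 0 genes past the threshold in limma, a count that all 35 reach by necessity, so it says nothing about chance. The highest other split, by number as above, gave 51. For genes at an unadjusted p under 0.05, 16 of 35 splits gave as many as the 569 of genotype, with up to 3285 for flox arrays 1 to 3 with WT array 2. For lists called by camera, 5 of 35 gave as many as 17, with up to 19. Chance was excluded for neither the count at an unadjusted p nor that of lists, and splits with several times the count of genotype point to a structure of the samples other than genotype.

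A floxed allele or DNA carried along with it could alter neighbouring genes. Of the 20 genes nearest to the floxed gene, 7 were tested, and 0 passed 0.05 adjusted over the set in limma (smallest adjusted p 0.672, 0 at an unadjusted p under 0.05). Their median absolute change of 0.07 lay at the 68.8th percentile of 14874 runs of as many neighbouring genes, so these 7 genes gave no sign of it. The other 13 were not tested.

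Mir300 and Mir382, among the genes with the smallest p, belong to the imprinted Dlk1-Dio3 cluster, as does Mir341 (0.19, SE 0.05), noticed with them, which led to the hypothesis that the cluster may be higher in flox as a whole. Of 25 tested genes of the cluster, 20 were higher and 7 of these had an unadjusted p under 0.05. Without these 3 microRNA genes, the other 22 shifted by 0.11 (SE 0.09, exact permutation p = 0.314), and by 0.06 without flox array 3. Their means were -0.119 and -0.049 on flox arrays 1 and 2 and 0.217 and 0.175 on flox arrays 3 and 4, against -0.096 to 0.020 on the WT arrays. A change shared along the cluster was thus not shown, and it was not excluded either. Only 0.172% of 14574 runs of as many neighbouring genes had as high a mean. That share is no test of chance, because the cluster was picked from these same data.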
